A study of Rattus norvegicus with 11 samples.

How the data were processed

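Islet RNA from female rats of the Sprague-Dawley strain was measured on 11 one-colour Affymetrix Rat Gene 1.0 ST arrays. Of these, 6 came from daughters of fathers fed chow (9% fat) and 5 from daughters of fathers fed a high-fat diet (HFD, 43% fat). The labels number the samples within each group but do not say that the numbers stand for separate rats, litters or fathers. The p-values therefore measure the spread between these samples, part of which may be technical. Arrays have no read depth, and the number of arrays limits the precision.

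The gene-level table holds log2 values that the authors had normalized between arrays before they were deposited. Their range and near-equal quartiles showed the log2 scale, which no header states. RMA and MAS5 are named in the submitters' processing notes, without a role, an order or a version. Background correction and probe summary are not given in the sources used here. Median log2 values ran from 6.137 to 6.202 over the arrays, and correlations between pairs of arrays from 0.9869 to 0.995. A second deposited table holds log2 values of 65535 exon-level features for 8 arrays, 4 per group. It ends at 65536 lines with its header, and 69.5% of the gene-level probes carry a higher number than its last feature, so it covers part of the array only. Its features were not paired with genes here, and none is named.

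The sample numbers fall into a run of 8 arrays and a later run of 3 (chow-father 5 and 6 and HFD-father 5). In every probe of the gene-level table, the mean over the later run equalled the mean over the earlier run to within 5.83e-05. For the other 164 sets of 3 arrays, the smallest median difference between such means was 0.0495. The values were therefore centred per run before deposit, a step found from the values and named in no label. Centring pulls a group difference toward 0 where groups are unequally spread over runs. Differences over all arrays were 0.978 times those of a fit with the run as a block, which centring does not affect.

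Of 27342 probes, 15097 had 1 gene symbol in the platform table, 323 had several and 11922 were not listed there and stay unnamed here. Symbols were updated through Entrez gene numbers to the RefSeq annotation of GRCr8 for 15067 probes. No coordinates from that build are printed. Control probes were not told apart from other unlisted probes, so none was removed. The probe with the highest mean over all arrays stood for each of the 14324 genes, 499 of which had more than 1 probe.

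Groups were compared with limma 3.58.1 (lmFit and eBayes, R 4.3.3), with no covariate, no filter on dim probes and two-sided p-values. Benjamini-Hochberg adjustment ran over all 27342 probes, with 0.05 as the threshold. Adjusted p-values of single genes are from limma unless said otherwise. Before the data were examined, 40 gene lists were fixed from textbook knowledge, covering islet cell types, other cell types an islet preparation can hold, metabolism, stress and signalling. They were tested with limma's camera at a preset correlation of 0.01 between genes, adjusted over the 40 lists. Camera with an estimated correlation, limma's fry and an exact permutation test of each list's mean over arrays, with HFD labels moved within runs in 210 splits, served as alternatives. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

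The rule for named genes was also fixed before the data were examined. It took up to 12 genes per direction past the threshold, filled to 8 per direction by lowest unadjusted p where fewer passed, and the 4 members of lowest p in each shifted list. Ins1, Ins2, Gcg, Sst, Pdx1, Mafa, Slc2a2 and Il13ra2 were added whatever their values, of which Pdx1 and Mafa were not analysed here. A further gene of the rule is not reported here. Placeholder symbols were left out. Any other gene named in the text was chosen after its values were seen.

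Data were simulated for the comparison of HFD-father with chow-father arrays (27342 probes, centred per run). In them, 100 probes were changed by 0.5 on the log2 scale and 100 by 1. Limma called 83% of the former and 95% of the latter. The adjusted threshold is stricter where fewer probes change, and recovery with fewer changed probes was not simulated. A count of 0 called genes therefore does not exclude differences of 0.5. Of the unchanged simulated probes, 1.34% had an unadjusted p under 0.01, against 0.962% with the run as a block. Camera, tested on 40 lists over 14324 simulated genes, called all 3 lists shifted by 0.3 on the log2 scale and 0 others. Its noise was independent between genes, and smaller shifts of lists were not simulated.

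Alternatives fixed in advance were a filter on dim probes, the replicate number or the run as a block, the first run alone, quantile normalization, median centring, array weights, eBayes with a trend, the acinar marker mean as covariate, the mean of a gene's probes, and each replicate left out. The second run alone, cyclic loess, the run block with quantile normalization, the count of identical probes as 1 and the permutation of list means were added after seeing the data.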

Results

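Islets of 13-week-old daughters of chow-fed and HFD-fed male rats were profiled to ask how a father's diet is reflected in his daughters' islet transcripts. Fathers were mated at 15 weeks of age with chow-fed females, and the daughters were weaned onto chow at 3 weeks. The labels describe the daughters of HFD-fed fathers as glucose intolerant with an impaired early insulin response. The arrays numbered 6 for chow fathers and 5 for HFD fathers. The first run held 4 arrays of each group, and the second 2 chow-father arrays and 1 HFD-father array. Values within the second run therefore have no replicate in the HFD-father arm. All differences are given as HFD-father minus chow-father on the log2 scale.

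Transcripts of the main islet hormones lay at nearly equal levels in both groups. Ins1, which encodes insulin, averaged 14.257 ± 0.054 (SD, n = 6) in chow-father and 14.268 ± 0.035 (SD, n = 5) in HFD-father arrays, a difference of 0.01 with a 95% interval from -0.09 to 0.11. The other insulin gene, Ins2, differed by 0.00 (interval -0.10 to 0.10), and the glucagon gene Gcg by 0.00 (interval -0.12 to 0.12). Somatostatin (Sst) differed by 0.00 with a wider interval, from -0.25 to 0.25, and by -0.11 without HFD-father replicate 3. Slc2a2, the glucose transporter of beta cells, was -0.08 (interval -0.28 to 0.11), and -0.02 without chow-father replicate 4. These transcripts sit near the top of the array's scale, where a difference in abundance can be compressed. Among the lists, islet hormones and granule proteins (17 genes) had a median difference of 0.00 and an adjusted camera p of 0.746, while its mean difference was -0.03. Beta cell transcription factors (13 of 23 genes measured) gave -0.02 (adjusted p = 0.616), and glucose sensing and insulin secretion (22 of 31 genes measured) gave -0.02 (adjusted p = 0.742). Without HFD-father replicate 1 these 3 medians were 0.03, 0.01 and 0.01. The median of the transcription factors was -0.04 without HFD-father replicate 5, and that of glucose sensing -0.05 without HFD-father replicate 3. None of the 3 lists passed.

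The single-gene comparison called 0 genes with limma, and the lowest adjusted p over all probes was 0.316. At an unadjusted p under 0.05 limma gave 1182 genes, against 716.2 expected by chance, and under 0.01 it gave 262 genes, against 143.2. Simulated unchanged probes centred per run reached a p under 0.01 in 1.34% of cases, so chance gives more than 143.2. A further 336 of 12245 probes with no single gene symbol here lay under 0.01. Ghrl, the gene of the hormone ghrelin, was among the lowest p-values. Its level was 6.264 ± 0.114 (SD, n = 6) in chow-father and 5.859 ± 0.174 (SD, n = 5) in HFD-father arrays, a difference of -0.41 ± 0.08 (SE) with an adjusted p of 0.316. Ghrl passed when adjusted over the list alone of islet hormones and granule proteins (adjusted p = 0.005). That adjustment was made in each of the 40 lists with no correction over lists, and 5 members of all lists passed. For Ghrl all 5 HFD-father arrays lay below the chow-father mean, which its choice by lowest p makes likely. The Ghrl difference was -0.35 within the first run and -0.61 within the second.

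Other genes of lowest unadjusted p with lower values under HFD fathers also failed the adjustment (adjusted p = 0.316). Dcdc1-ps1, a pseudogene, differed by -0.57 and Adgre4, an adhesion G protein-coupled receptor of myeloid cells, by -0.42. The carbonic anhydrase gene Car7 differed by -0.40 and Or13p4, an olfactory receptor gene, by -0.31. S1pr5, a receptor for sphingosine-1-phosphate, Atoh1, a transcription factor of secretory and neural lineages, and Ccn5, a matricellular protein gene, gave -0.30, -0.30 and -0.29. For each of these 7 genes all 5 HFD-father arrays lay below the chow-father mean. Their choice by lowest p makes this likely, so it is no separate support.

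Genes of lowest unadjusted p with higher values under HFD fathers differed by 0.35 at most. Hpdl differed by 0.35, Tacc3, which acts at the mitotic spindle, by 0.32, and the homeobox gene Hoxc5 by 0.28. Hivep1 differed by 0.25, Tubb3, a tubulin of neurons, by 0.24, Ankmy2 by 0.24, Fam186b by 0.24 and Zfp868 by 0.21. Adjusted p-values ran from 0.316 for Tubb3 to 0.357 for Ankmy2. All 5 HFD-father arrays exceeded the chow-father mean for each of the 8, which their choice by lowest p also makes likely.

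Il13ra2, a receptor for interleukin 13 and a gene singled out in the published study of these animals, averaged 2.950 ± 0.228 (SD, n = 6) in chow-father and 3.768 ± 0.649 (SD, n = 5) in HFD-father arrays. The difference was 0.82 ± 0.24 (SE), with a 95% interval of 0.30 to 1.33. It did not pass (adjusted p = 0.41 with limma). Values lay above the chow-father mean in 4 of 5 HFD-father arrays, and the difference was 0.80 within the first run and 0.95 within the second. With each replicate left out it ran from 0.61 (without HFD-father replicate 1) to 1.03 (without HFD-father replicate 2). HFD-father 1 held the highest value, 4.586, and also had the highest lymphocyte marker mean of all arrays. Only 6.5% of probes had a lower mean level, and no test set this probe against background, so the size of the difference in transcript abundance is uncertain. Because the study chose this gene on these samples, its direction here is not independent evidence.

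**Figure D1:**
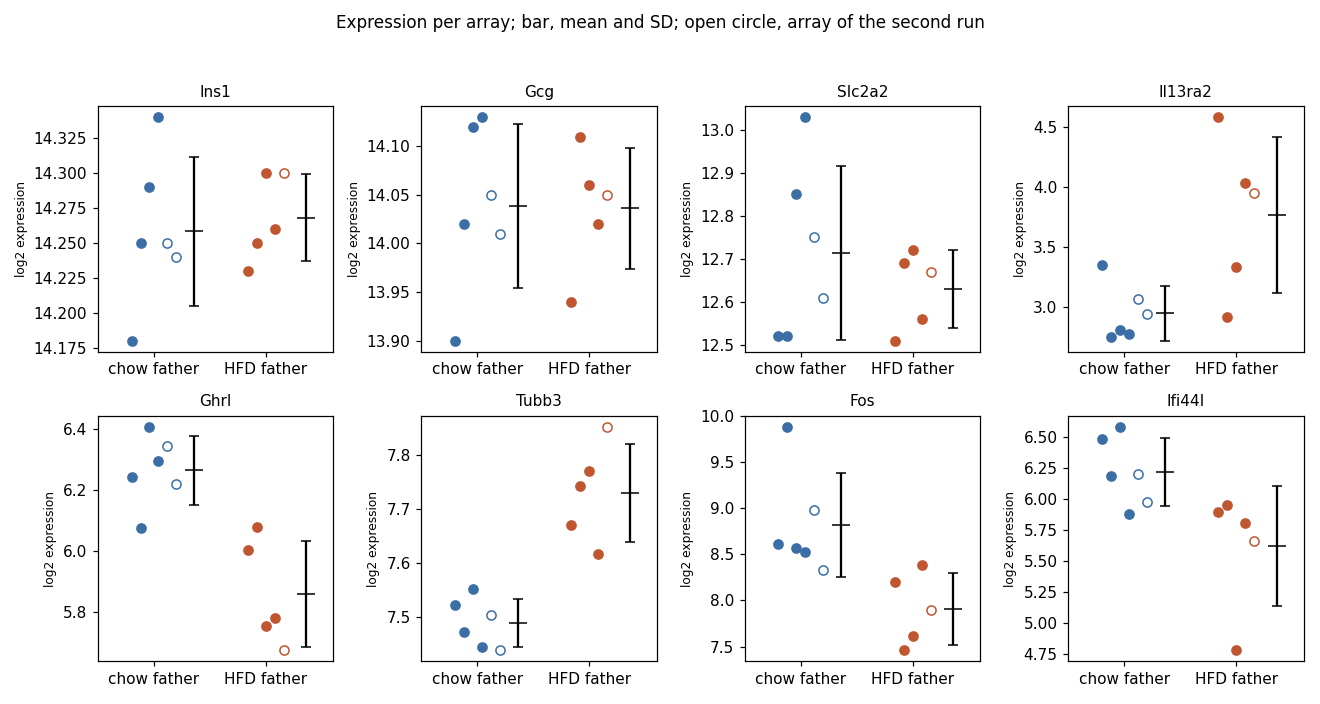
Log2 expression of 8 named genes in each array (filled circles, first run; open circles, second run), with the mean and SD of the chow-father (n = 6) and HFD-father (n = 5) groups; the vertical scale differs between panels. The group means of Ins1 and Gcg differ by 0.01 and 0.00, while Ghrl lies lower and Il13ra2 higher on average in HFD-father arrays (-0.41 and 0.82), neither past the adjusted threshold.

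Among the 262 genes at an unadjusted p under 0.01, 73 were higher and 189 lower in HFD-father arrays, so 72.1% were lower. The split depended on the scaling of the arrays and on the filter. Without dim probes 73 genes were higher and 52 lower (41.6% lower). The numbers were 85 higher and 114 lower (57.3% lower) after quantile normalization, 126 and 100 (44.2%) after median centring, and 102 and 101 (49.8%) after cyclic loess. Without HFD-father replicate 5 the count was 119 and without HFD-father replicate 1 it was 417. With the run as a block 184 genes lay under 0.01 (74.5% lower), and in the first run alone 114 did (76.3% lower). The counts of 119 and 114 lie below the 143.2 expected by chance. The HFD-father arrays had a wider spread of values on average. Their interquartile range was 3.069 ± 0.053 (SD, n = 5) against 2.996 ± 0.041 (SD, n = 6), with a two-sided exact permutation p of 0.0476 within runs. The range was widest in HFD-father 4 and 5 (3.123 and 3.121), while HFD-father 1 at 3 and HFD-father 2 at 3.042 lay below chow-father 3 at 3.048. The contrast of bright minus dim probes was higher by 0.05 in HFD-father arrays, with a two-sided exact permutation p of 0.0524 within runs, which misses 0.05. The median difference was -0.01 in the lowest decile of mean expression, -0.06 in the 4th and 0.03 in the 9th.

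**Figure D2:**
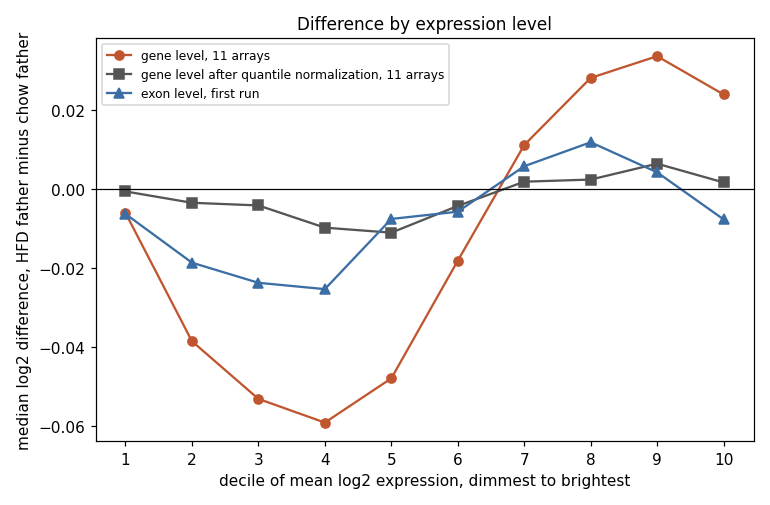
Median log2 difference (HFD-father minus chow-father) of probes in each decile of mean log2 expression, for the deposited gene-level values, the same values after quantile normalization and the exon-level values of the first run. In the deposited gene-level values the median runs from -0.06 in the 4th decile to 0.03 in the 9th.

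By camera with a preset correlation, 8 of the 40 gene lists shifted, 3 lower and 5 higher in HFD-father arrays, and with the run as a block the count was also 8. With an estimated correlation between genes 0 lists passed, the lowest adjusted p being 0.148. Fry gave 0 lists (lowest adjusted p = 0.121), as did the exact permutation test of list means (lowest adjusted p = 0.381). After quantile normalization 3 lists passed, namely immediate early genes, interferon response and lymphocyte markers, of which the last is not among the 8, and cyclic loess gave the same 3. Without dim probes the 3 that passed were immediate early genes, olfactory receptors and proteasome. The count was 4 without chow-father replicate 4 and 14 without HFD-father replicate 3. In the test of change in either direction, fry passed Schwann and nerve markers (adjusted p = 0.0356), of which Cdh19 differed by 0.17, Gfap by -0.24, Foxd3 by -0.19 and Ngfr by -0.17. Those members were chosen after their values were seen.

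Immediate early genes, which cells transcribe within minutes of a stimulus, fell as a list in HFD-father arrays, with 20 of 21 measured members lower and a median difference of -0.18 (limma's camera, adjusted p = 1.2e-05). The adjusted p was 0.952 with an estimated correlation. Fos differed by -0.91 ± 0.25 (SE), Nr4a1 by -0.81 ± 0.32, Egr1 by -0.52 ± 0.19 and Egr4 by -0.21 ± 0.07. No member passed over all genes, and 0 passed when adjusted over the list alone. The list median was -0.17 within the first run (adjusted p = 3.13e-05) and -0.18 within the second. Nr4a1 differed by -1.17 within the first run and 0.20 within the second. The mean of the list over arrays gave an exact permutation p of 0.152 within runs.

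The interferon response list also fell, with 29 of 37 measured members lower and a median of -0.13 (adjusted camera p = 0.00131, and adjusted p = 0.952 with an estimated correlation). Usp18, which restrains interferon signalling, differed by -0.30 ± 0.08 (SE), the antiviral gene Oasl by -0.22 ± 0.07, Ifi44l by -0.60 ± 0.20 and the chemokine gene Cxcl11 by -0.62 ± 0.25. Ifi44l was -0.39 without HFD-father replicate 3, and Cxcl11 was -0.40 without chow-father replicate 3. None of the members passed over all genes or adjusted over the list alone. The list median was -0.17 within the first run (adjusted p = 7.15e-06) and 0.08 within the second. Without dim probes it was -0.05 (adjusted p = 0.121) and without chow-father replicate 3 it was -0.06 (adjusted p = 0.0585), and neither passed.

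Olfactory receptor genes, a large family at or near the dim end of the array, fell by 0.04 in the median, with 712 of 1098 lower (adjusted camera p = 0.000899, and adjusted p = 0.148 with an estimated correlation). Olr36 differed by -0.34, Or52n2e by -0.28 and Or51k7 by -0.19. The median was -0.04 within the first run (adjusted p = 0.0107) and -0.04 within the second. After quantile normalization it was -0.02 and did not pass (adjusted p = 0.274). The median level of the list was 3.84. Over all probes, the median difference was -0.01 in the lowest decile of mean expression (level 3.15) and -0.04 in the 2nd (level 4.1). The fall of the list was therefore not told apart from that of dim probes in general.

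Proteasome genes rose as a list, with 26 of 30 higher and a median of 0.06 (adjusted camera p = 0.000899, and adjusted p = 0.952 with an estimated correlation). Psmd14 differed by 0.17 ± 0.06 (SE), Psmc6 by 0.15 ± 0.07, Psma5 by 0.15 ± 0.09 and Psmb5 by 0.08 ± 0.05. Psma5 was 0.01 within the first run, and 0.07 without HFD-father replicate 5. The list median was 0.03 within the first run (adjusted p = 0.119) and 0.15 within the second, and 0.04 after quantile normalization (adjusted p = 0.106). TCA cycle genes rose by a median of 0.05, with 21 of 22 higher (adjusted camera p = 0.0123, and adjusted p = 0.952 with an estimated correlation). Idh1, the cytosolic dehydrogenase of isocitrate, differed by 0.23 ± 0.08, Sucla2 by 0.14, Sdha by 0.10 and Dlat by 0.08. Of the list, Idh1 alone had an unadjusted limma p under 0.05. Idh1 was 0.15 without HFD-father replicate 4, Sucla2 0.09 without HFD-father replicate 2 and Sdha 0.06 without chow-father replicate 4. Within the first run the TCA median was 0.05 (adjusted p = 0.0382) and within the second 0.04. It did not pass without chow-father replicate 4 (adjusted p = 0.0636), without HFD-father replicate 2 (adjusted p = 0.12) or after quantile normalization (adjusted p = 0.298).

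Genes of cholesterol and fatty acid synthesis rose as a list, with 18 of 21 higher and a median of 0.07 (adjusted camera p = 0.0105, and adjusted p = 0.952 with an estimated correlation). Insig1, a sterol-regulated membrane protein, differed by 0.23 ± 0.09 (SE), Idi1 by 0.24 ± 0.12, Msmo1 by 0.18 ± 0.10 and Fdft1 by 0.11 ± 0.05. Without HFD-father replicate 4 Idi1 was 0.13, Msmo1 0.10 and the list median 0.04, and without HFD-father replicate 1 the median was 0.116. The median was 0.06 within the first run (adjusted p = 0.0555) and 0.08 within the second. It did not pass without chow-father replicate 4 (adjusted p = 0.0758), without HFD-father replicate 2 (adjusted p = 0.0678), without HFD-father replicate 4 (adjusted p = 0.0913) or after quantile normalization (adjusted p = 0.0898).

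**Figure D3:**
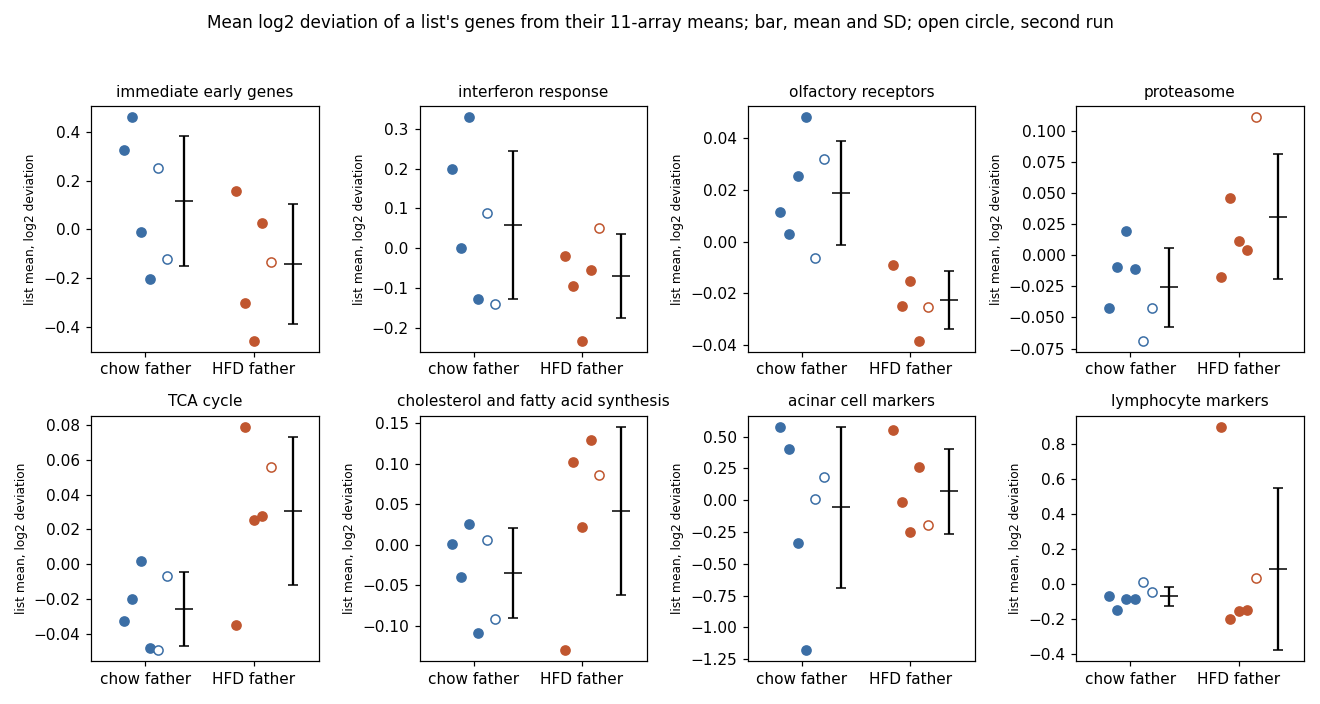
Mean log2 deviation of the genes of 8 lists from their means over 11 arrays, per array (filled circles, first run; open circles, second run), with the mean and SD of the chow-father (n = 6) and HFD-father (n = 5) groups; the vertical scale differs between panels. Acinar markers range from -1.18 in chow-father 4 to 0.574 in chow-father 1, and lymphocyte markers stand at 0.899 in HFD-father 1.

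Markers of other cell types varied between arrays. Acinar cell markers, the digestive enzyme genes of the exocrine pancreas, rose by a median of 0.18, with 24 of 29 higher (adjusted camera p = 0.0335, and adjusted p = 0.994 with an estimated correlation). Cela1 differed by 0.35 ± 0.29 (SE), Cela2a by 0.25 ± 0.22, Rnase1 by 0.21 ± 0.16 and Pnlip by 0.18 ± 0.15. Without chow-father replicate 4 these were 0.12, 0.05, 0.05 and 0.04. Their list mean ranged from -1.18 in chow-father 4 to 0.574 in chow-father 1. The median was 0.28 within the first run (adjusted p = 8.75e-05) and -0.11 within the second. It was 0.274 without chow-father replicate 1, 0.08 without HFD-father replicate 1 and 0.01 without chow-father replicate 4 (adjusted p = 0.955), and the list also lost its call without chow-father replicate 3 (adjusted p = 0.306) or without HFD-father replicates 1, 2 or 4 (adjusted p = 0.619, 0.0603 and 0.188). It was 0.09 after quantile normalization (adjusted p = 0.134), and no call was made without dim probes (median 0.175, adjusted p = 0.423) or after cyclic loess (median 0.171, adjusted p = 0.113).

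Endothelial cell markers rose by a median of 0.09, with 13 of 14 higher (adjusted camera p = 0.0228, and adjusted p = 0.994 with an estimated correlation). Tie1, a receptor of endothelial cells, differed by 0.18 ± 0.08 (SE), Plvap by 0.17 ± 0.08, Flt1 by 0.10 ± 0.07 and Emcn by 0.10 ± 0.07. Without HFD-father replicate 1 Plvap was 0.11 and Emcn 0.04, and without HFD-father replicate 5 Flt1 was 0.06. The median was 0.07 within the first run (adjusted p = 0.0668) and 0.16 within the second. It was 0.145 without HFD-father replicate 3 and 0.05 without HFD-father replicate 1 (adjusted p = 0.534), and the call was also lost without chow-father replicate 4 (adjusted p = 0.221), without chow-father replicate 6 (adjusted p = 0.18), after quantile normalization (median 0.0913, adjusted p = 0.0561) and with the acinar marker mean as covariate (median 0.0801, adjusted p = 0.0995). Ductal, stellate and fibroblast, macrophage and lymphocyte markers did not pass (adjusted p = 0.981, 0.516, 0.981 and 0.15). The lymphocyte list, with a median of 0.08, gained a call after quantile normalization (0.13, adjusted p = 0.019). Its median was -0.03 without HFD-father replicate 1 (adjusted p = 0.219).

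The exon-level table was compared in its 4 chow-father and 4 HFD-father arrays, which all belong to the first run. Limma called 0 of 65535 features (lowest adjusted p = 0.628). At an unadjusted p under 0.05 there were 3405 features, and under 0.01 there were 656, against 655.4 expected by chance. Of the 656 features, 311 were higher and 345 lower in HFD-father arrays.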

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

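Quantile normalization and the first run alone were fixed in advance as alternatives. Their use to test explanations of the share of lower genes was chosen after that share had been seen. Quantile normalization and the permutation test were likewise chosen afterwards as tests for the immediate early genes.

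Single arrays stood apart from the rest of their group in 6 of 140 groups of values, where chance flags about 1 in 20. The stellate cell and fibroblast marker mean was -0.259 in HFD-father 3 and between 0.0514 and 0.158 in the other HFD-father arrays. Rnase1, an acinar ribonuclease gene, stood at 9.426 in chow-father 4, below 10.24 to 10.55 in the rest of its group. Ifi44l was 4.781 in HFD-father 3, against 5.663 to 5.953. Cxcl11 was 7.919 in chow-father 3, against 6.404 to 6.894. The proteasome gene Psmd14 was 8.221 in chow-father 5, against 8.34 to 8.404.

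The lymphocyte marker mean was 0.899 in HFD-father 1, and the next highest of all arrays was 0.033. Ptprc, the leukocyte antigen CD45, stood at 9.089 there and between 5.616 and 6.908 elsewhere, and the T cell kinase gene Lck at 7.03 against 5.802 to 6.204. Of 18 measured markers, 15 had their highest value in that array, a count favoured by picking the array with the highest list mean. Lymphoid cells in the sample, which may have come with pancreatic lymph nodes or infiltrated islets, are a candidate source. Of the markers, 3 lay above the median probe in the other arrays and 0 belong to another list. Marker means of macrophages (0.449), endothelial cells (0.28) and ductal cells (0.271) were also highest in HFD-father 1, while those of acinar and stellate cells were not. The next highest means of these 3 lists were 0.311 in chow-father 3, 0.117 in chow-father 5 and 0.197 in chow-father 1. High marker means in HFD-father 1 were therefore not confined to lymphocytes, but the margin was much larger for the lymphocyte list. An intensity-dependent shift is argued against, since the lymphocyte marker mean was still 0.879 after quantile normalization. A difference that follows from the father's diet stays untested, because 1 array shows the pattern.

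The excess of lower genes under HFD fathers (72.1% of 262 at an unadjusted p under 0.01) may come from an intensity-dependent difference left between the arrays, since the share was 57.3% after quantile normalization. Acinar RNA as the whole cause is argued against by a share of 68% with the acinar marker mean as covariate. Centring per run is argued against by a share of 76.3% within the first run, which centring does not affect. The 114 genes of that run are fewer than the 143.2 expected by chance, however. Chance was not tested for the share itself. Most other divisions of the 11 arrays, drawn at random, had a smaller share in their larger direction. Some exceeded it, for example with 78% of 418 genes and 74% of 246. An effect of the father's diet stays open and untested.

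The fall of the immediate early genes was not removed by quantile normalization (list median -0.159) or by the acinar covariate (-0.216), which argues against either as the whole cause. The exact permutation p of 0.152 leaves open variation between arrays that the genes of the list share, for example from how long each islet isolation took, which these data cannot test. The father's diet also stays open and untested.

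Chance could not be excluded for the count of genes at an unadjusted p under 0.01 or for that of gene lists. At an unadjusted p under 0.01, 11 of 100 splits, the real one included, gave at least the 262 genes of the real split, with 665 in the highest other. That split set chow-father 3 and 4 with HFD-father 3, 4 and 5 and points to a structure of the samples. Its sides differed by 0.624 in the acinar marker mean and by 0.286 in the next list, immediate early genes; whether either accounts for the 665 genes was not tested. For gene lists, 66 of 100, the real one included, gave at least 8 (highest other 18). The splits were drawn without regard to the runs. Centring pulls differences toward 0 in splits that spread the runs unevenly, so the count of 11 may be too low. The real split called 0 genes and 0 exon-level features, a count that 100 of 100 and 35 of 35 splits reach by necessity (highest others 2 and 0), so these splits say nothing about chance.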

How the results depend on the processing

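The second run alone, the run block with quantile normalization, cyclic loess, the count of identical probes as 1 and the permutation of list means were chosen after seeing the data. Limma called 0 genes under every alternative run. The count at an unadjusted p under 0.01 (262) was 125 without dim probes, 114 in the first run, 102 in the second run and 138 with the run block and quantile normalization. Leaving out each replicate gave 119 (without HFD-father 5) to 417 genes (without HFD-father 1). In place of 8 shifted lists there were 3 without dim probes, 3 after quantile normalization, 3 with the run block and quantile normalization and 3 after cyclic loess. The last 3 settings each held lymphocyte markers, which are not among the 8. The second run gave 3, with the acinar list in the opposite direction; it holds 1 HFD-father array, assumed to vary like the others, so its values have no replicate in that arm. There were 0 with camera's estimated correlation, 0 with fry and 0 by exact permutation. The exact permutation could hardly give another count, since 1 list alone could not pass after adjustment. Leaving out each replicate gave 4 (without chow-father 4) to 14 lists (without HFD-father 3). Fewer arrays or probes entered the filtered, single-run and left-out fits; otherwise the cause was not tested.

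The acinar list turned under camera without chow-father replicate 4 (median 0.00806, against up to 0.274 without chow-father replicate 1) and in the second run (-0.108), and the interferon list in the second run (0.0792); the cause was not tested. With camera at the preset correlation, and the second run left out, immediate early genes passed in 20 of 20 alternatives, interferon response in 18, olfactory receptors in 17, proteasome in 16, the TCA cycle in 14, cholesterol synthesis in 11 and endothelial markers in 10, and acinar markers in 10 of 19; with an estimated correlation none passed. None of the 1306 values of the 53 named genes under alternatives passed the threshold. The sign of 9 genes changed under some alternative (Ins1, Ins2, Gcg, Sst, Cela1, Cela2a, Pnlip, Nr4a1 and Cxcl11). Exon-level calls ranged from 0 to 1 with each replicate left out, with 1 without chow-father 4 and 1 without HFD-father 1.

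Equal replicate numbers were not shown to pair the samples. Deviations of same-numbered arrays correlated at 0.33, -0.0306, 0.00477, -0.0247 and -0.318 for numbers 1, 2, 3, 4 and 5. Number 1 exceeded its best correlation with another number (0.152). Numbers 2, 3 and 4 fell below theirs (0.264, 0.321 and 0.175). For number 5 the test cannot decide, because centring per run sets the deviations of second-run arrays against each other (correlations from -0.595 to -0.436). With the replicate block limma called 0 genes, with 165 at an unadjusted p under 0.01 and 6 lists (those of cholesterol synthesis and endothelial markers lost their call), and 0 exon-level features. The exon table averaged to genes was not run because its features were not paired with genes, nor was a run block for it, since it holds 1 run. Signal over background was not measured here, which limits what can be said of dim genes such as Il13ra2.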

Other observations

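The mast cell list tested here was written after Cpa3 and Mcpt1l1 had been seen, and all genes named below were chosen after their values were seen. Only 4 genes differed by more than 1 on the log2 scale. Cpa3, the carboxypeptidase of mast cell granules, was 3.437 ± 0.570 (SD, n = 6) in chow-father and 4.538 ± 0.792 (SD, n = 5) in HFD-father arrays, a difference of 1.10 (adjusted p = 0.43), and 5 of 5 HFD-father arrays lay above the chow-father mean. HFD-father 2 did so only narrowly, at 3.463, and chow-father 1 (4.468) exceeded HFD-father 1 (4.462). The highest values were in HFD-father 4 and 5 (5.364 and 5.255). Without either of these the difference was 0.894 and 0.921. Mcpt1l1, a mast cell protease gene, differed by 1.22 (adjusted p = 0.487, 4 of 5 arrays higher), with its highest value, 7.404, in HFD-father 4. Cxcl13, a chemokine that draws B cells, differed by 1.38 ± 0.57 (SE, adjusted p = 0.494, 4 of 5 arrays higher). A1bg, a plasma glycoprotein gene, differed by -1.25 ± 0.28 (SE, adjusted p = 0.319, 5 of 5 arrays lower). None passed the threshold.

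Some genes passed only when adjusted over the list alone, with no correction over the 40 lists. Slc38a5, an amino acid transporter gene in the alpha cell list, was higher by 0.19 (adjusted p = 0.0285, 5 of 5 arrays higher). The methylation and histone list held Dnmt3l, a partner of DNA methyltransferases, at -0.35 and Suv39h1, a histone H3 methyltransferase gene, at -0.27 (adjusted p = 0.0374 for both, 5 of 5 arrays lower). Gfap, expressed by Schwann cells around islets, was -0.24 (adjusted p = 0.0153, 5 of 5 arrays lower). All 4 failed over all probes, with limma's adjusted p from 0.362 to 0.38.

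As a hypothesis, mast cells in the HFD-father samples may lie behind Cpa3 and Mcpt1l1. Of 18 measured mast cell markers, 16 were left without that pair, and 10 of the 16 were higher. Their run-adjusted mean difference was 0.0601 ± 0.0356 (SE), with a two-sided exact permutation p of 0.124 within runs, so the test left the hypothesis open. The granule protease gene Cma1 differed by 0.46, while the tryptase genes Tpsab1 and Tpsb2 differed by -0.01 and 0.03. Many of these markers lie at the dim end of the array, where a small number of cells need not show.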
